A study of Bos taurus with 12 samples.

How the data were processed

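Whole blood of 12 female cattle had been collected in PAXgene tubes, and total RNA had been isolated with the matching blood RNA kit and checked on a Bioanalyzer. Labelled cRNA had been made from 5 µg of total RNA with the Quick Amp kit (Cy3, 1 colour) and hybridised to Agilent bovine arrays. The cattle had been tested with a commercial antibody ELISA for MAP and with faecal PCR for IS900 and ISMap02. Groups were taken from the sample labels. Per the file headers, the 12 arrays lay on 3 slides, each with 1 array of each group and each scanned on its own day, so that the replicate number, the slide and the scan day were the same factor.

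Per the file headers, the scanner files held spot intensity from Agilent Feature Extraction 11.0.1.1, with no normalization between arrays, and the design of the array followed the bovine build UMD 3.1. The deposited matrix held log2 values of 29011 probes, and the method by which the authors normalized it was not given in the sources used here. Each array had 45220 spots, of which 43803 were for bovine probes and 1417 were controls. The 75th percentile of the signal ranged from 1541 to 2556, the number of spots marked as outliers from 2 to 21 and the median coefficient of variation of the spike-in controls from 8.85% to 13.6%. Log2 signals of the arrays correlated at 0.967 to 0.991. Gene symbols came from the array annotation and a reference table for the build ARS-UCD2.0, which was used for names and for the order of neighbouring genes. Of 43653 distinct probes, 26743 had 1 symbol (12603 symbols) and 16910 had none.

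Spots marked as outliers were left out, the spots of each of the 50 probes printed 4 times were averaged, and the 75th percentile of each array was subtracted from the log2 signal. The 32882 probes well above background on at least 3 of the 12 arrays were tested. Limma 3.58.1 (lmFit and eBayes, R 4.3.3) fitted the means of the 4 groups to all 12 arrays, with no covariate. All tests were two-sided, and p values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. Fold changes carry their standard error from this fit. The 10 comparisons were each test-positive group and their mean against CON, the ELISA and PCR effects, their interaction, and the 3 pairs of test-positive groups. The design, the gene lists, the rule for named genes and most other ways of processing were fixed before the data were examined.

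The deviations of the arrays from their group means correlated at a mean of 0.262 for arrays of the same slide (0.00416 to 0.519, 18 pairs) and at -0.131 for arrays of different slides (36 pairs). Every result was therefore also fitted with the slide as a block, which left the fold changes as they were and lowered the median residual SD from 0.276 (8 degrees of freedom) to 0.188 (6 degrees of freedom). The first principal component held 26.7% of the variance (57.5% of it between groups, 36.1% between slides) and the second 17.5% (73% of it between slides).

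Named genes followed a rule. One probe stood for each gene, the one with the highest mean signal. For each comparison against CON, up to 12 genes in each direction with the largest fold changes were named among genes that passed, were well above background on every array of at least 1 group and did not overlap between groups, filled up to 8 with genes of smallest p. In the other comparisons the numbers were 6 and 3. Up to 4 members of lists that passed were added as examples, of which some are printed, and a panel of IFNG, IL10, TNF, IL1B, IL17A, CXCL8 and TLR2. CCR9 for ELISA status and probes without a gene name were added after their values were seen. Some genes that the rule names are not reported here. Where a probe was not well above background on any array of 1 group, the fold change is given as a lower bound. This bound allows for the dim signal alone and not for the spread between animals, so the difference may be smaller.

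For 28 gene lists, camera with a preset correlation of 0.01 was run on 10592 genes with 1 probe each, and p values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A list had to have at least 5 measured members, and of the 22 measured T helper and regulatory genes 21 entered the test, because 1 lacked a value on an array. Counts of members adjusted over the list alone used the p values of the members only. A list score was the mean over its genes of the signal centred over the 12 animals. List means are unweighted. Some lists shared members. FCGR1A was in the monocyte, complement and interferon-gamma lists, CTSB in the monocyte and phagosome lists and BLK in the B cell and gamma-delta lists. Lists that passed are therefore not independent of each other.

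Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, median scaling, the deposited matrix, other filters on dim probes, the slide block, array weights, eBayes with trend and robust, the compared arrays alone, the mean of the probes of a gene, other thresholds, and leaving out each array in turn. The mean spot signal planned for normexp was not used here and the median spot signal took its place. In a simulation on 32836 probes with 100 changed probes for each fold, 57% of 2-fold and 94% of 4-fold changes were recovered for ELISA status (73% and 95% with the slide block), and 32% and 81% for Test3 against CON (53% and 90% with the slide block). The unchanged probes called were 1 and 8 for ELISA status and 3 and 10 for Test3, without and with the block. The noise was drawn apart for each probe, so structure shared by probes was left out. These counts may therefore be too low for the real arrays. A shift of 0.7 in the monocyte list was estimated as 0.758 for ELISA status and 0.661 for Test3. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and gene symbols for the lists were read with jsonlite 2.0.0.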

Results

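Gene expression was measured in the peripheral blood of 12 female cattle, with 1 single-colour oligonucleotide array per animal. The animals were grouped by 2 tests for Mycobacterium avium subsp. paratuberculosis (MAP), the bacterium of Johne's disease, a chronic intestinal infection of ruminants. An ELISA detected MAP-specific antibodies and a PCR on faeces detected MAP DNA. Control cattle (CON) were negative in both tests, Test1 cattle were positive by PCR only, Test2 cattle by ELISA only and Test3 cattle by both, with 3 animals in each group. Per array, 68.5% to 74.6% of the spots for bovine probes were well above background, the median signal lay between 183 and 296 and no spot was saturated. The 3 animals per group limit the precision of every comparison. The 4 groups allowed ELISA status, PCR status and their combination to be compared.

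The first question was how ELISA-positive cattle (Test2 and Test3) differed from ELISA-negative cattle (CON and Test1). IGFLR1, which encodes a receptor for insulin-like growth factor-like proteins, rose the most of the named genes. Its probe (A_73_100575) averaged 3.24 ± 0.52 (SD, n = 6) in ELISA-positive and -0.92 ± 0.20 (SD, n = 6) in ELISA-negative animals, in log2 units relative to the 75th percentile of each array. That is a log2 fold change of 4.16 ± 0.21 (SE; limma adjusted p = 4.07e-05), or 17.8-fold. GSTO1, an omega-class glutathione transferase, rose by 1.18 ± 0.12 (SE, adjusted p = 0.00534), from 1.32 ± 0.18 to 2.51 ± 0.15 (SD, n = 6 each). CLEC4A, an inhibitory lectin receptor of myeloid cells, rose by 1.67 ± 0.23 (adjusted p = 0.0307). ULBP3, a ligand of the activating receptor NKG2D of cytotoxic lymphocytes, fell by 2.43 ± 0.29 on the log2 scale (adjusted p = 0.0213).

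DNAH9, a dynein heavy chain of cilia, also rose in ELISA-positive cattle, by 2.42 ± 0.25 (SE, n = 6 against 6, adjusted p = 0.0064), although it was well above background in only 3 of the 6 ELISA-negative animals. PHACTR3, a phosphatase and actin regulator, was not well above background in any ELISA-negative animal and was at least 2.23-fold higher in ELISA-positive animals (adjusted p = 0.0352). The homeobox gene PBX4 rose by 1.03 ± 0.16 (adjusted p = 0.0389). Among genes that fell, MAPT (the microtubule-associated protein tau) changed by -1.11 ± 0.16, FSTL1 (a secreted glycoprotein) by -0.97 ± 0.13 and DPP4 (the T cell surface peptidase CD26) by -0.93 ± 0.14. SPINT2, a serine protease inhibitor, changed by -0.88 ± 0.13 and LPAR3, a receptor for lysophosphatidic acid, by -0.78 ± 0.12. Their adjusted p values lay between 0.0307 and 0.0402, and the other probe of SPINT2 lay on the other side of 0.

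In all, 75 of 32882 probes passed for ELISA status, 39 higher and 36 lower, and 6679 had an unadjusted p under 0.05. With the slide as a block 2873 probes passed, 1370 higher and 1503 lower, among them all 75. The count depended on single animals: it was 8, 12 and 6 without CON replicates 1, 2 and 3, 30, 1221 and 9 without Test1 replicates 1, 2 and 3, 7 and 9 without Test2 replicates 1 and 3, and 666, 13 and 50 without Test3 replicates 1, 2 and 3. IGFLR1, DNAH9 and GSTO1 passed in each of these 12 fits, whereas ULBP3 passed in 6, CLEC4A and FSTL1 in 5, MAPT, PHACTR3 and LPAR3 in 3 and DPP4, PBX4 and SPINT2 in 2. With the slide block the count was 10, 3 and 1 without CON replicates 1, 2 and 3, 52 and 9 without Test1 replicates 1 and 3, 42, 4972 and 1 without Test2 replicates 1, 2 and 3, and 1912, 27 and 1452 without Test3 replicates 1, 2 and 3. Test1 replicate 2 had the lowest share of spots well above background (68.5%) and the highest SD of the negative controls (4.80). Its spike-in coefficient of variation was also the highest (13.6%, against 13.4% in Test2 replicate 2). The quality of this array and the state of this animal cannot be told apart here.

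**Figure D1:**
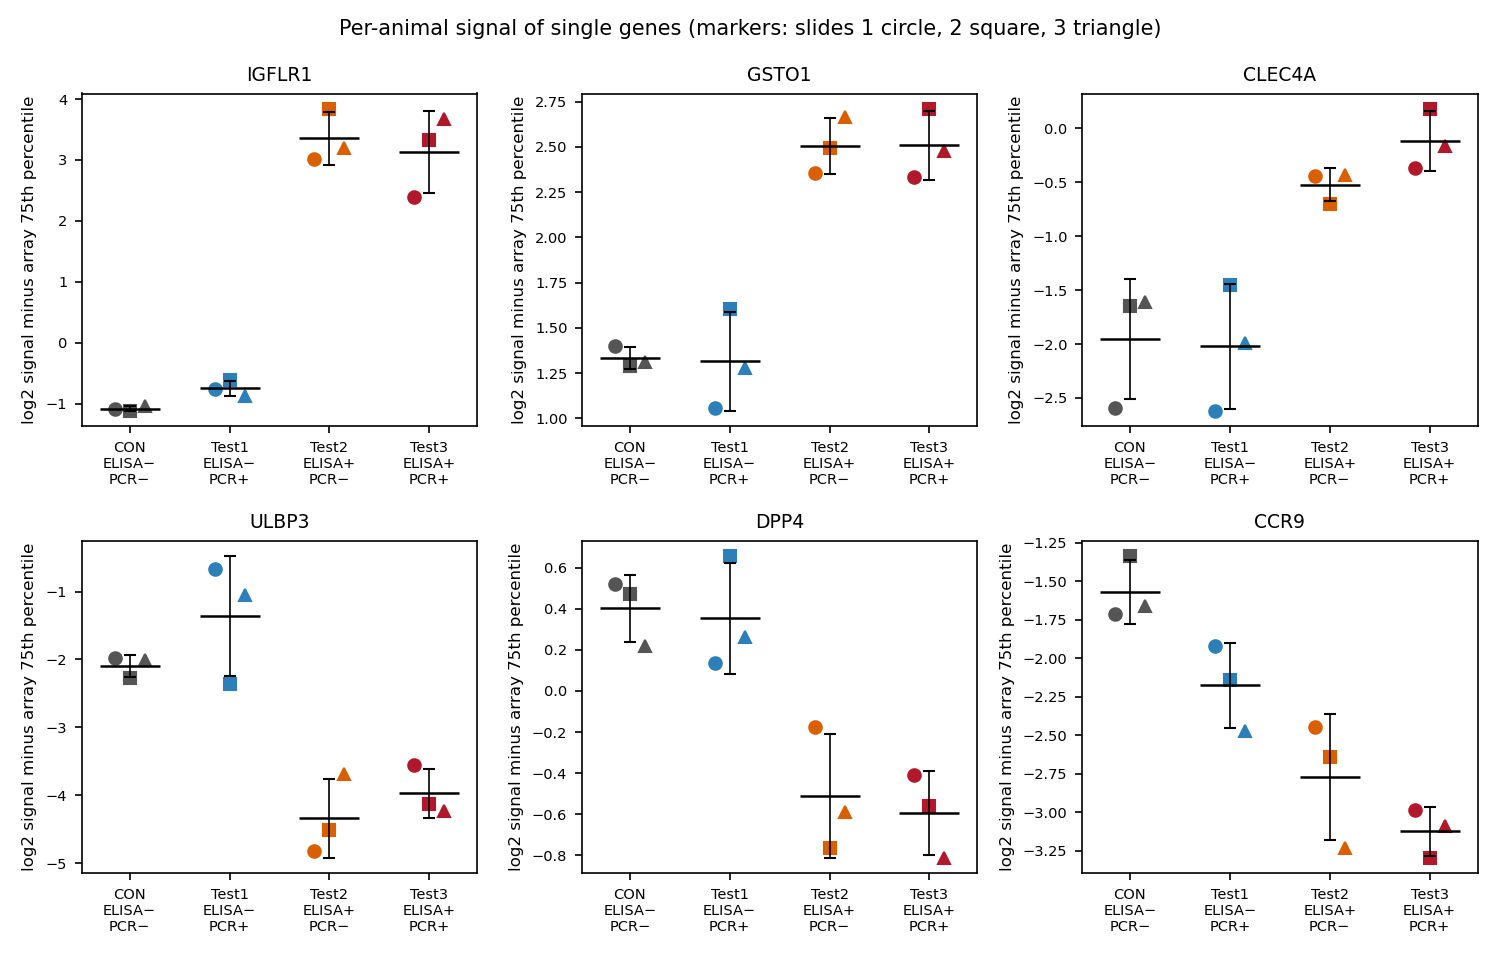
Signal of 6 genes in each animal (y axes, log2 signal minus the 75th percentile of the array) by group (x axes), with points for single animals, bars for the group mean ± SD and marker shapes for the 3 slides. IGFLR1 averaged 3.35 in Test2 and 3.13 in Test3 against -1.08 in CON and -0.75 in Test1; CCR9 passed for ELISA status (log2 fold change -1.08, adjusted p = 0.0341) but not in Test2 or Test3 against CON without the slide block (adjusted p = 0.207 and 0.0702).

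Monocyte and macrophage genes rose together in ELISA-positive cattle. All 22 measured members lay above 0 and the mean of the list was 0.74 higher on the log2 scale (camera adjusted p = 1.18e-09, adjusted p = 0.204 with an estimated correlation). The per-animal score was 0.37 ± 0.30 in ELISA-positive and -0.37 ± 0.42 in ELISA-negative cattle (SD, n = 6 each). Over all genes 1 member passed (8 with the slide block), and 12 passed adjusted over the list alone. CD68, a lysosomal glycoprotein of macrophages, rose by 0.80 ± 0.13 (SE, adjusted p = 0.0402), and passed in 2 of the 12 fits that each left out 1 array. The growth factor receptor CSF1R stood at 0.91 ± 0.21 (adjusted p = 0.0818, 0.0454 with the block) and the matrix protein gene TGFBI at 0.67 ± 0.18 (adjusted p = 0.0948, 0.0455 with the block).

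Complement and Fc receptor genes rose by a mean of 0.65 (20 of 23 members above 0, adjusted p = 5.63e-07, adjusted p = 0.204 with an estimated correlation). None of them passed over all genes (9 with the slide block) and 13 were higher adjusted over the list alone. FCER1G, the Fc receptor gamma chain, stood at 0.69 ± 0.13 (SE, adjusted p = 0.06, 0.0227 with the block), complement C3 at 0.82 ± 0.18 (0.0781, 0.0432 with the block) and C1QC at 1.72 ± 0.40 (0.0829, 0.0415 with the block). Pattern recognition genes rose by a mean of 0.38 (22 of 31 above 0, adjusted p = 2.29e-05, adjusted p = 0.204 with an estimated correlation), with 1 member past the threshold over all genes (9 higher and 1 lower with the slide block) and 13 higher adjusted over the list alone. The fungal glucan receptor CLEC7A rose by 0.99 ± 0.16 (adjusted p = 0.0402) and passed in 3 of the 12 fits without 1 array. The endotoxin receptor TLR4 stood at 0.70 ± 0.13 (adjusted p = 0.0647, 0.0303 with the block). Phagosome, oxidase and lysosome genes rose by a mean of 0.25 (31 of 36 above 0, adjusted p = 5.63e-07, adjusted p = 0.204 with an estimated correlation), with none past the threshold over all genes (9 with the slide block) and 12 higher and 2 lower adjusted over the list alone. The oxidase subunit NCF4 stood at 0.71 ± 0.18 (adjusted p = 0.092, 0.0437 with the block).

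Neutrophil granule and antimicrobial peptide genes rose by a mean of 0.70 (23 of 24 above 0, adjusted p = 9.46e-06) and neutrophil markers by 0.31 (18 of 21, adjusted p = 0.00014). Inflammatory cytokines and chemokines rose by 0.40 (19 of 24, adjusted p = 0.00077) and metalloproteinases with their inhibitors and matrix genes by 0.38 (17 of 20, adjusted p = 0.00192). The adjusted p was 0.204 with an estimated correlation for each of these 4 lists. No member passed over all genes (4, 4, 4 and 1 with the slide block), and 5, 4, 5 and 4 were higher adjusted over the list alone. The beta-defensin DEFB4A stood at 1.89 ± 0.35 (SE, adjusted p = 0.0643, 0.0285 with the block), neutrophil elastase (ELANE) at 1.01 ± 0.24 (0.0834, 0.0433 with the block) and the IL-1 receptor antagonist IL1RN at 0.52 ± 0.11 (0.0768, 0.036 with the block).

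T cell and B cell genes fell in ELISA-positive cattle. T cell markers changed by a mean of -0.38 (24 of 25 below 0, adjusted p = 1.91e-08, adjusted p = 0.204 with an estimated correlation). None passed over all genes (9 lower with the slide block) and 13 were lower adjusted over the list alone. The signalling adaptor LAT stood at -0.50 ± 0.09 (SE, adjusted p = 0.0644, 0.0254 with the block), the T cell receptor zeta chain CD247 at -0.63 ± 0.14 (0.0755, 0.0364 with the block) and the interleukin-7 receptor IL7R at -0.74 ± 0.18 (0.0851, 0.033 with the block). B cell markers changed by a mean of -0.43 (12 of 12 below 0, adjusted p = 9.65e-05, adjusted p = 0.309 with an estimated correlation), with none past the threshold over all genes (2 lower with the slide block) and 2 lower adjusted over the list alone. Gamma-delta T cell markers changed by -0.95 (5 of 5 below 0, adjusted p = 0.0135, adjusted p = 0.415 with an estimated correlation), in this direction on 2 of 3 slides, and no member passed in either fit. BLK, 1 of the 5, was also in the B cell list. CD163L1 and WC1.3 stood at 4.98 and 2.31 in Test1 replicate 1 but at 0.721 and -1.89 in Test1 replicate 2.

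Genes of red cells and platelets moved with these leukocyte lists. Erythroid and reticulocyte genes rose by a mean of 0.71 (23 of 27 above 0, adjusted p = 0.000139, adjusted p = 0.4 with an estimated correlation), on 2 of 3 slides, with none past the threshold over all genes (2 with the slide block) and 5 adjusted over the list alone. Platelet and megakaryocyte genes rose by 0.41 (13 of 16, adjusted p = 0.00077, adjusted p = 0.252 with an estimated correlation), with none past the threshold over all genes (1 with the slide block) and 2 adjusted over the list alone. Oxidative phosphorylation genes rose by 0.07 (34 of 43 above 0, adjusted p = 0.049, adjusted p = 0.709 with an estimated correlation). This call held in 5 of the 12 fits that each left out 1 array, with the mean at 0.04 without Test1 replicate 1 and 0.11 without Test3 replicate 1. None of its members passed over all genes or adjusted over the list alone.

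The other 14 lists did not pass for ELISA status. Type I interferon-stimulated genes had a mean of 0.00 and a median of -0.07 (adjusted p = 0.965), so that mean and median differed in sign. Interferon-gamma response genes had a mean of 0.21 (adjusted p = 0.107) and MHC class II genes 0.09 (adjusted p = 0.0783). The class II mean was lowered by BOLA-DQA5, which was high in CON replicates 1 and 3 only (3.65 and 2.48). MHC class I genes had a mean of 0.24 and a median of 0.02 (adjusted p = 0.935). That mean came largely from JSP.1 (3.52 ± 2.13, SE, adjusted p = 0.383), and was 0.11 without Test1 replicate 2. T helper and regulatory T cell genes had a mean of -0.10 (adjusted p = 0.108), plasma cell and immunoglobulin genes 0.04 (adjusted p = 0.559), NK and cytotoxic genes 0.25 (adjusted p = 0.0552) and eosinophil and basophil genes 0.18 (adjusted p = 0.163). Sterol genes had a mean of -0.08 (adjusted p = 0.25), lipid handling genes 0.23 (adjusted p = 0.0736) and apoptosis genes 0.09 (adjusted p = 0.0552). Cell cycle genes stood at -0.05 (adjusted p = 0.441), immediate early and heat shock genes 0.17 (adjusted p = 0.0937) and ribosomal protein genes -0.05 (adjusted p = 0.142, 0.0445 with the slide block, 0.804 with the block and an estimated correlation). Adjusted over the list alone, 5 immediate early, 4 lipid, 3 apoptosis and 1 class II genes were higher and 2 lipid genes and 1 gene each of the T helper, sterol and plasma cell lists lower. Of the fits that each left out 1 array, NK genes passed in 7 of 12 (mean 0.11 without Test3 replicate 1 to 0.31 without Test2 replicate 1), ribosomal protein genes in 5 (-0.10 without Test3 replicate 3 to 0.03 without Test2 replicate 1) and apoptosis genes in 4 (0.07 to 0.12). MHC class II genes passed in 3 (0.03 without Test3 replicate 2 to 0.19 without Test3 replicate 1), as did lipid handling genes (0.16 to 0.31). Interferon-gamma and immediate early genes passed in 2 each, T helper and cell cycle genes in 1 each and the other 5 lists in none. Means on both sides of 0 were seen for type I interferon genes (-0.10 without Test2 replicate 3 to 0.07 without Test2 replicate 1). The same held for cell cycle genes (-0.13 without Test3 replicate 1 to 0.02 without Test3 replicate 3). It also held for plasma cell genes (-0.02 without Test3 replicate 1 to 0.10 without Test3 replicate 2). The transcription factor JUN stood at 0.81 ± 0.14 (SE, adjusted p = 0.0545, 0.0227 with the block) and PPARG, a lipid-sensing nuclear receptor, at 0.97 ± 0.22 (0.0817, 0.0254 with the block). The rotation test fry, which asks whether a list moves one way on balance, passed 10 of the 28 lists and 11 with the slide block.

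**Figure D2:**
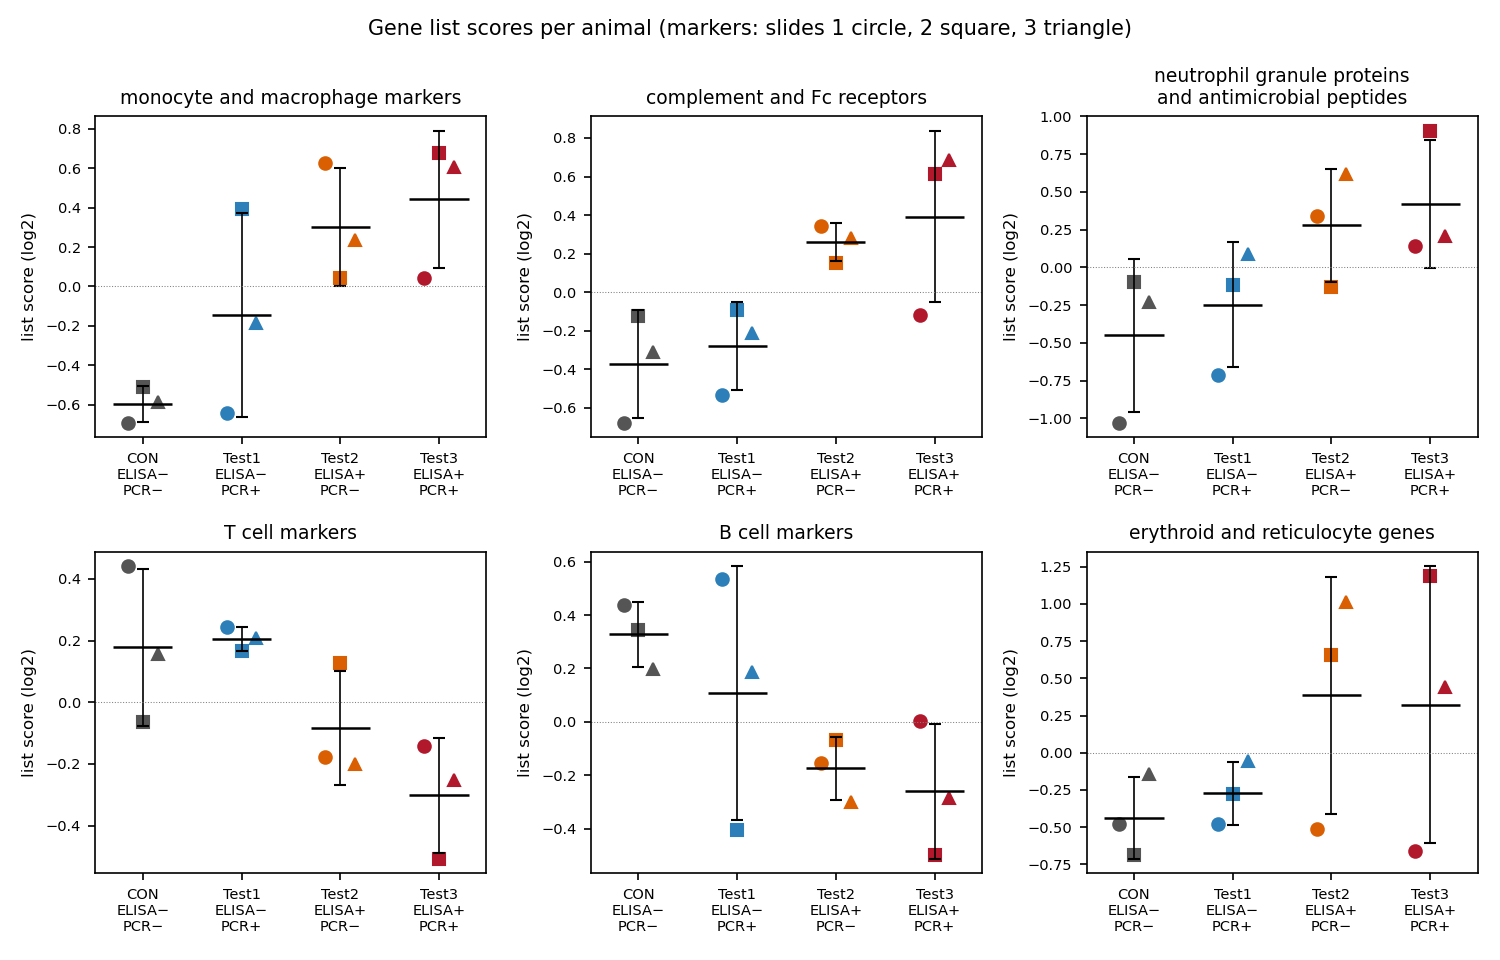
Scores of 6 gene lists in each animal (y axes, mean over the genes of the list of the log2 signal centred over the 12 animals) by group (x axes), with points for single animals, bars for the group mean ± SD and marker shapes for the 3 slides. The monocyte score averaged 0.37 in ELISA-positive and -0.37 in ELISA-negative cattle, and Test1 replicate 2 stood at 0.39.

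Test3 cattle, positive in both tests, were then compared with CON (3 animals each). IGFLR1 rose by 4.21 ± 0.30 on the log2 scale (SE, adjusted p = 0.00123), to 3.13 ± 0.67 (SD, n = 3) from -1.08 ± 0.04 (SD, n = 3). The unnamed probe A_73_P251776 fell by 5.01 ± 0.45 (adjusted p = 0.00564), and the unnamed probe A_73_P489303, not well above background in CON, was at least 2.43-fold higher (adjusted p = 0.00905). These were the 3 probes that passed, and 5170 had an unadjusted p under 0.05. With the slide as a block, 417 probes passed (257 higher, 160 lower, 235 named genes), including the same 3.

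Several genes that missed the threshold without the block (adjusted p between 0.0702 and 0.111) passed with it. GSTO1 stood at 1.17 ± 0.16 (SE, adjusted p = 0.0702, 0.0406 with the block), CD68 at 1.19 ± 0.18 (0.0702, 0.0406 with the block), CLEC7A at 1.46 ± 0.22 (0.0702, 0.0413 with the block) and ACSL6, which activates long-chain fatty acids, at 1.61 ± 0.25 (0.0702, 0.0429 with the block). B3GNT3, a glycosyltransferase, stood at 1.07 ± 0.18 and NUDCD1, whose other probe lay below 0, at 0.83 ± 0.14. CCL24, an eosinophil chemoattractant not well above background in CON, was at least 2.65-fold higher (adjusted p = 0.0754, 0.0406 with the block). On the lower side, CCR9, a chemokine receptor of gut-homing lymphocytes, stood at -1.55 ± 0.22 (0.0702, 0.0406 with the block), KANK4 at -3.11 ± 0.45, PPP1R13L at -1.09 ± 0.18, NDRG4 at -1.43 ± 0.25, ELL3 at -1.11 ± 0.20, FAAP20 at -0.61 ± 0.11 and CRTC1 at -0.67 ± 0.13. The adhesion molecule VCAM1, not well above background in Test3, was at least 2.35-fold lower (adjusted p = 0.11, 0.0525 with the block). Of the cytokines and receptors often measured in bovine paratuberculosis, IL1B stood at 0.67 ± 0.23 (adjusted p = 0.206), IFNG at 0.23 ± 0.55 (0.899), IL10 at 0.19 ± 0.36 (0.864), TNF at 0.15 ± 0.21 (0.799), CXCL8 at -0.36 ± 0.71 (0.871) and TLR2 at 0.01 ± 0.14 (0.984). The probe of IL17A was too dim to be tested.

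Most of the leukocyte lists that passed for ELISA status also passed in Test3, but gamma-delta T cell genes (-0.84) did not (adjusted p = 0.095). Monocyte genes rose by a mean of 1.04 (22 of 22 above 0, adjusted p = 2.2e-11, adjusted p = 0.235 with an estimated correlation), with none past the threshold over all genes (2 with the slide block) and 11 adjusted over the list alone. Complement and Fc receptor genes rose by 0.76, phagosome genes by 0.31, pattern recognition genes by 0.49, granule genes by 0.87, neutrophil markers by 0.39 and metalloproteinase genes by 0.53 (adjusted p between 6.62e-07 and 0.000584, adjusted p = 0.235 with an estimated correlation for each). Adjusted over the list alone, 11, 10, 12, 1, 1 and 3 of their members were higher and 1 phagosome and 1 pattern recognition gene lower, against none over all genes (2, 1, 3, 2, 0 and 0 with the slide block). T cell genes changed by -0.48 (24 of 25 below 0, adjusted p = 4.76e-08, adjusted p = 0.235 with an estimated correlation; 10 lower adjusted over the list alone). B cell genes changed by -0.59 (12 of 12, adjusted p = 1.91e-05, adjusted p = 0.333 with an estimated correlation; 4 lower adjusted over the list alone). Inflammatory genes rose by 0.37 (adjusted p = 0.0143, adjusted p = 0.365 with an estimated correlation; 8 adjusted over the list alone). Lipid handling genes rose by 0.33 (adjusted p = 0.0147, adjusted p = 0.365 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone) and oxidative phosphorylation genes by 0.10 (adjusted p = 0.0157, adjusted p = 0.761 with an estimated correlation). This last call held in 9 of the 12 fits that each left out 1 array, with means of 0.06, 0.08 and 0.05 where it was lost (without CON replicate 1, Test3 replicate 2 and Test3 replicate 3) and 0.19 without Test3 replicate 1. The inflammatory mean was 0.23 without CON replicate 1. The platelet call was lost without Test3 replicate 1 (0.37), and the lipid call without CON replicate 3 (0.33, adjusted p = 0.0504). Erythroid genes rose beside them by 0.76, on 2 of 3 slides (adjusted p = 0.000687, adjusted p = 0.465 with an estimated correlation), and platelet genes by 0.40 (adjusted p = 0.0106, adjusted p = 0.376 with an estimated correlation). With fry 6 of the 28 lists passed, and 10 with the slide block.

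In Test3 against CON, the number of called probes rose to 296 without Test3 replicate 1, to 24 without Test1 replicate 2 and to 6 without Test1 replicate 1 or any 1 of the 3 Test2 animals. It was 2 without CON replicate 1 and 1 without CON replicate 3 or Test3 replicate 2. With the slide block the count of 417 became 2144 without Test2 replicate 2, 851 without Test2 replicate 1, 778 without Test1 replicate 2, 129 without Test1 replicate 1 and at most 49 without any 1 of the others. IGFLR1 passed in all 12 of the fits without the block. The mean of the erythroid list was 1.25 without Test3 replicate 1 and 0.32 without Test3 replicate 2.

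Test2 cattle, positive by ELISA only, showed the same leading gene against CON (3 animals each). IGFLR1 rose by 4.43 ± 0.30 (SE, adjusted p = 0.000732), to 3.35 ± 0.43 (SD, n = 3). The unnamed probe A_73_P251776 fell by 4.99 ± 0.45 (adjusted p = 0.00581). No other probe passed, while 2989 had an unadjusted p under 0.05 and 5 passed with the slide block (3 higher, 2 lower). VSIG2, an immunoglobulin-domain surface protein, stood at 1.75 ± 0.28 and passed with the block alone (adjusted p = 0.197, 0.0202 with the block).

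Other genes of smallest p did not pass in Test2. GSTO1 stood at 1.17 ± 0.16 (SE, adjusted p = 0.125), DMKN at 2.30 ± 0.37, TFAP2C at 2.18 ± 0.38, CLEC7A at 1.29 ± 0.22 and B3GNT3 at 1.05 ± 0.18 (adjusted p between 0.196 and 0.207). CCL24, not well above background in CON, was at least 2.63-fold higher (adjusted p = 0.196). CHORDC1 stood at -0.86 ± 0.16, CCR9 at -1.20 ± 0.22, ULBP3 at -2.25 ± 0.41, NDRG4 at -1.33 ± 0.25, KANK4 at -2.37 ± 0.45, ELL3 at -1.02 ± 0.20 and the ruminant MHC class II gene BOLA-DYB at -0.93 ± 0.19 (adjusted p between 0.207 and 0.272). VCAM1 was at least 2.32-fold lower (adjusted p = 0.207). IFNG stood at 0.67 ± 0.55, IL10 at 0.18 ± 0.36, TNF at 0.19 ± 0.21, IL1B at 0.27 ± 0.23, CXCL8 at -0.05 ± 0.71 and TLR2 at -0.10 ± 0.14 (adjusted p between 0.752 and 0.992).

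Monocyte genes rose by a mean of 0.90 in Test2 (22 of 22 above 0, adjusted p = 5.64e-12, adjusted p = 0.374 with an estimated correlation; 7 adjusted over the list alone). Complement and Fc receptor genes rose by 0.63, granule genes by 0.73, phagosome genes by 0.24, pattern recognition genes by 0.40 and metalloproteinase genes by 0.41 (adjusted p between 3.62e-05 and 0.00126, adjusted p = 0.374 with an estimated correlation for each). Of their members 7, 0, 0, 4 and 0 were higher adjusted over the list alone. B cell genes changed by -0.50 (12 of 12 below 0, adjusted p = 1.03e-05, adjusted p = 0.374 with an estimated correlation). T cell genes changed by -0.26 (24 of 25, adjusted p = 7.12e-05, adjusted p = 0.424 with an estimated correlation), and in both lists no member passed adjusted over the list alone. Neutrophil markers rose by 0.20, inflammatory genes by 0.31 and lipid handling genes by 0.31 (adjusted p = 0.0172, 0.0351 and 0.0351, adjusted p = 0.424 with an estimated correlation for each). Oxidative phosphorylation genes rose by 0.09 and cell cycle genes changed by -0.13 (adjusted p = 0.0333 and 0.0347, adjusted p = 0.697 with an estimated correlation for both). Granule and cell cycle genes moved this way on 2 of 3 slides, as did T cell genes, and the calls for neutrophil, inflammatory, lipid, oxidative phosphorylation and cell cycle genes held in 10, 9, 10, 8 and 9 of the 12 fits that each left out 1 array. Without CON replicate 1 the T cell mean was -0.13, the granule mean 0.44, the inflammatory mean 0.18, the oxidative phosphorylation mean 0.04 and the cell cycle mean -0.05. Without Test2 replicate 3 the last 2 were 0.02 and -0.24, and without Test2 replicate 1 the oxidative phosphorylation mean was 0.16. Without Test2 replicate 2 the cell cycle mean was -0.06. Over all genes no member of any of these lists passed, and with fry no list did (lowest adjusted p = 0.12), with or without the slide block. Erythroid genes rose with them by 0.82, on 2 of 3 slides (adjusted p = 0.000163, adjusted p = 0.424 with an estimated correlation), and by 0.51 without Test2 replicate 3 and 1.27 without Test2 replicate 1. Platelet genes rose by 0.43 (adjusted p = 0.00229, adjusted p = 0.42 with an estimated correlation), and by 0.24 without Test2 replicate 3. Ribosomal protein genes had a mean of 0.07 and passed with the slide block (adjusted p = 0.094, 0.0138 with the block, 0.734 with the block and an estimated correlation). Their mean was above 0 on 2 of 3 slides, and was -0.02 without Test2 replicate 3 and 0.22 without Test2 replicate 1. The count of 2 probes became 14 without Test1 replicate 2, 5 without Test3 replicate 1 and 1 without CON replicate 3 or Test2 replicate 3. The 5 with the slide block became 793 without Test2 replicate 2, 12 without Test3 replicate 1, 3 without Test1 replicate 3 or Test3 replicate 3, 1 without CON replicate 1 or Test2 replicate 3 and 0 without CON replicate 3 or Test2 replicate 1.

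Test1 cattle, positive by PCR only, differed from CON in no single probe that passed in limma (0 of 32882 probes, smallest adjusted p = 0.0927, 1238 with an unadjusted p under 0.05). The count was also 0 with the slide block, against 4 after another background correction. In the deposited matrix the count was 122, and 11 with the slide block. The ruminant class II gene BOLA-DYB stood at -1.46 ± 0.19 (SE, n = 3 against 3, adjusted p = 0.0973) and the p53-binding regulator PPP1R13L at -1.35 ± 0.18 (adjusted p = 0.0973). FBXL16, an F-box protein gene, was not well above background in Test1 and was at least 2.37-fold lower (adjusted p = 0.0927). VCAM1 and LRRC49 were likewise at least 2.03-fold and at least 2.01-fold lower (adjusted p = 0.172 for both).

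Further genes in Test1 had adjusted p values of 0.232 or more. KANK4 stood at -2.75 ± 0.45 (SE), ANGPTL4, an inhibitor of lipoprotein lipase, at -1.04 ± 0.17 and RNF141 at -0.96 ± 0.16. On the higher side B3GNT3 stood at 1.01 ± 0.18, ZPR1 at 0.67 ± 0.12, PRKCI at 0.86 ± 0.19, MGST2 at 1.17 ± 0.27, FMNL2 at 0.67 ± 0.16, ERG at 0.74 ± 0.18, FASTKD3 at 1.41 ± 0.35 and NRN1 at 1.39 ± 0.36. IFNG was not well above background in Test1. Its mean was at least 2.5-fold lower than in CON, a difference that did not pass (adjusted p = 1). On slide 2 IFNG stood at -5.84 in CON and -5.88 in Test1. IL10, TNF, IL1B, CXCL8 and TLR2 stood at -0.06, 0.22, 0.18, -0.02 and -0.03 (adjusted p = 1 for each).

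Some gene lists passed in Test1. Monocyte genes rose by a mean of 0.45 (21 of 22 above 0, adjusted p = 4.42e-06, adjusted p = 0.811 with an estimated correlation), but by 0.18 without Test1 replicate 2, where the list no longer passed (adjusted p = 0.186), and by 0.70 without Test1 replicate 1. Ribosomal protein genes rose by 0.14 (71 of 72, adjusted p = 4.42e-06, adjusted p = 0.914 with an estimated correlation), and by 0.21 without Test1 replicate 1. They stood at 0.04 without Test1 replicate 3 and 0.05 without CON replicate 1, where the call was lost. MHC class II genes changed by -0.58 (10 of 14 below 0, adjusted p = 0.00118, adjusted p = 0.811 with an estimated correlation; 3 lower adjusted over the list alone). Much of this mean came from BOLA-DQA5 (-4.86 ± 1.47, SE, adjusted p = 1), and the median of the list was -0.27. BOLA-DQA5 was high in CON replicates 1 and 3 (3.65 and 2.48) but stood at -2.29 in CON replicate 2. In Test1 it lay between -4.93 and -2.84. Interferon-gamma response genes changed by -0.20 (15 of 19, adjusted p = 0.00118, adjusted p = 0.811 with an estimated correlation), and stood at -0.09 without Test1 replicate 1, where the call was lost. B cell genes changed by -0.22 (10 of 12, adjusted p = 0.00204, adjusted p = 0.91 with an estimated correlation), on 2 of 3 slides, and by -0.44 without Test1 replicate 1. They stood at 0.04 without Test1 replicate 2, and the call held in 10 of the 12 fits that each left out 1 array. Lipid handling genes rose by 0.18 (24 of 37, adjusted p = 0.0457, adjusted p = 0.897 with an estimated correlation), on 2 of 3 slides, and by 0.32 without Test1 replicate 1. They stood at 0.04 without Test1 replicate 2, and this call held in 8 of the 12 fits. Test1 replicate 2 was the array with the lowest share of spots well above background (68.5%). Erythroid and platelet genes did not pass in Test1, and no list passed with fry (lowest adjusted p = 0.593), with or without the slide block. Of these 6 lists, no member passed over all genes, and outside the class II list 1 lipid gene was lower adjusted over the list alone. The count of called probes was 3 without Test3 replicate 3, and 1 without CON replicate 2, Test2 replicate 3 or Test3 replicate 1.

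The mean of the 3 test-positive groups was also compared with CON (9 animals against 3). IGFLR1 rose by 2.99 ± 0.25 (SE, adjusted p = 0.00495), and its 3 groups ranged from -0.75 to 3.35. Another 4 probes passed, none with a gene name. The unnamed probe A_73_P251776 fell by 3.97 ± 0.37 (adjusted p = 0.00753), A_73_P489303 was at least 1.63-fold higher (adjusted p = 0.0155), and the other 2 were lower (adjusted p = 0.031). PPP1R13L stood at -1.09 ± 0.15 (adjusted p = 0.0612, 0.0369 with the slide block) and B3GNT3 at 1.05 ± 0.15 (0.0724, 0.0369 with the block). BOLA-DYB stood at -1.12 ± 0.15 (0.065, 0.0427 with the block), KANK4 at -2.74 ± 0.37 (0.0612, 0.0527 with the block) and CLEC7A at 1.17 ± 0.18 (0.0931, 0.0567 with the block). Of the probes, 3661 had an unadjusted p under 0.05, and 53 passed with the slide block (35 higher, 18 lower). Among the lists, 11 rose and 2 fell, none of them with an estimated correlation (lowest adjusted p = 0.354) or with fry (lowest adjusted p = 0.0775). Monocyte genes led at 0.80 (adjusted p = 1.56e-12, adjusted p = 0.354 with an estimated correlation; 10 adjusted over the list alone). B cell genes stood at -0.44 (adjusted p = 9.69e-06, adjusted p = 0.394 with an estimated correlation; 4 lower adjusted over the list alone), beside erythroid genes at 0.58, on 2 of 3 slides (adjusted p = 0.00122, adjusted p = 0.54 with an estimated correlation). Ribosomal protein genes (0.06) passed with the slide block (adjusted p = 0.0713, 0.00524 with the block, 0.823 with the block and an estimated correlation). The count of 5 was 140 without Test3 replicate 1, 10 without Test1 replicate 1 and 0 without CON replicate 3, where IGFLR1 had an adjusted p of 0.0763; it was 2 without CON replicate 1 and 3 without Test1 replicate 2 or 3 or Test2 replicate 1 or 2. The 53 with the slide block became 1206 without Test2 replicate 2, 176 without Test3 replicate 1 and at most 29 without any 1 of the others.

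For PCR status (Test1 and Test3 against CON and Test2, 6 animals each) no probe passed in limma, with or without the slide block. The smallest adjusted p was 0.728, and 790 probes had an unadjusted p under 0.05 (1733 with the slide block). In the values of the deposited matrix 14 passed, and 0 with the slide block. CTXN3, a small neuronal membrane protein, stood at -1.34 ± 0.33 and CEND1 at -0.23 ± 0.08 (SE, adjusted p = 1 for both). Monocyte genes rose by a mean of 0.30 (20 of 22 above 0, adjusted p = 1.35e-06, adjusted p = 0.705 with an estimated correlation), and pattern recognition genes by 0.11 (adjusted p = 0.00552, adjusted p = 0.705 with an estimated correlation), both on 2 of 3 slides. B cell genes changed by -0.15 (adjusted p = 0.00552, adjusted p = 0.803 with an estimated correlation), in this direction on 1 of 3 slides. Of the 11 lists that passed, cell cycle genes (0.07), MHC class II genes (-0.31, median -0.11) and T cell genes (-0.09) did not pass with the slide block (adjusted p = 0.0535, 0.0801 and 0.0535; with an estimated correlation and no block, adjusted p = 0.803, 0.705 and 0.803). Cell cycle genes moved this way on 2 of 3 slides, as did oxidative phosphorylation genes (0.03) and ribosomal protein genes (0.02), which passed with the block (adjusted p = 0.0826 and 0.209, 0.0406 and 0.0471 with the block, 0.848 and 0.852 with the block and an estimated correlation). No list passed with fry (lowest adjusted p = 0.978).

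Among ELISA-positive cattle, those with a positive PCR (Test3) were compared with those without (Test2, 3 animals each). No probe passed in limma, with or without the slide block or in the deposited matrix, and 218 had an unadjusted p under 0.05. CCDC54, not well above background in Test2, had a mean at least 2.33-fold higher in Test3 and did not pass. The inflammatory caspase CASP4 stood at 0.33 ± 0.10 (SE), the follicle-homing receptor CXCR5 at -0.77 ± 0.24, the phosphatidate phosphatase LPIN1 at -0.94 ± 0.30 and SPDEF at -0.74 ± 0.23, with an adjusted p of 1 for each. T cell genes changed by a mean of -0.22 (24 of 25 below 0, adjusted p = 3.81e-07) and cell cycle genes by 0.16 (26 of 29 above 0, adjusted p = 6.7e-07), both on 2 of 3 slides and both with an adjusted p = 0.52 with an estimated correlation. Type I interferon-stimulated genes rose by 0.12 (18 of 24, adjusted p = 0.000404, adjusted p = 0.52 with an estimated correlation), also on 2 of 3 slides. In all 8 lists rose and 3 fell, none of them with an estimated correlation (lowest adjusted p = 0.52) or with fry (lowest adjusted p = 0.918). The sterol list (-0.11) did not pass with the slide block (adjusted p = 0.0341, 0.0778 with the block, adjusted p = 0.64 with an estimated correlation).

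ELISA status was then compared among PCR-positive cattle (Test3 against Test1, 3 animals each). IGFLR1 rose by 3.88 ± 0.30 (SE, adjusted p = 0.00282). XPNPEP3, a mitochondrial aminopeptidase, rose by 2.11 ± 0.24 (adjusted p = 0.0225). DNAH9 and FBXL16 were not well above background in Test1 and were at least 3.65-fold and at least 2.62-fold higher in Test3 (adjusted p = 0.0225 for both), calls that ended with the slide block (adjusted p = 0.0718 and 0.0735). FBXL16 averaged -4.99 in CON, -7.63 in Test1, -4.53 in Test2 and -4.84 in Test3, so Test1 alone stood apart and ELISA-negative CON did not. XPNPEP3 averaged -3.27 in CON, -4.54 in Test1, -2.57 in Test2 and -2.43 in Test3. DNAH9 averaged -5.86 in CON, -7.70 in Test1 and -4.36 in both Test2 and Test3. For both genes CON lay between Test1 and the ELISA-positive groups, so part of the rise came from low values in Test1. XPNPEP3, DNAH9 and FBXL16 passed in 6, 7 and 5 of the 12 fits that each left out 1 array, and IGFLR1 in all. The unnamed probe A_73_100847 rose by 1.82 ± 0.23 (adjusted p = 0.047, 0.0825 with the block) and A_73_P081658 fell by 2.10 ± 0.23 (adjusted p = 0.0225, 0.0718 with the block). FSTL1 stood at -1.31 ± 0.19, ZPR1 at -0.80 ± 0.12 and ULBP3 at -2.61 ± 0.41 (adjusted p = 0.0854, 0.107 and 0.114). These 6 probes were 5 higher and 1 lower, against 3808 with an unadjusted p under 0.05. With the slide block 3 probes passed, of which 2 were among these 6. T cell genes changed by -0.51 (23 of 25 below 0, adjusted p = 5.32e-10). Inflammatory genes rose by 0.50 and MHC class II genes by 0.37 (14 of 14, adjusted p = 0.000153 and 0.000563). Each of these 3 had an adjusted p = 0.174 with an estimated correlation, beside erythroid genes at 0.59 (adjusted p = 0.00159, adjusted p = 0.46 with an estimated correlation). The class II and erythroid lists moved this way on 2 of 3 slides. In all 14 lists rose and 5 fell, none of them with an estimated correlation (lowest adjusted p = 0.174) or with fry (6 with fry and the slide block). The count of 6 became 194 without Test1 replicate 2 (43 higher, 151 lower), 2 without Test1 replicate 1 or Test3 replicate 2 and 1 without CON replicate 3, Test1 replicate 3 or Test3 replicate 3.

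Test2 against Test1 compared cattle positive by ELISA only with cattle positive by PCR only. IGFLR1 rose by 4.10 ± 0.30 (SE, n = 3 against 3, adjusted p = 0.00161) and XPNPEP3 by 1.98 ± 0.24 (adjusted p = 0.0293). DNAH9 and FBXL16 were at least 3.65-fold and at least 3.24-fold higher (adjusted p = 0.0123 for both), calls that ended with the slide block (adjusted p = 0.0867 for both). The FBXL16 mean in CON (-4.99) lay near that in Test2 (-4.53), so this gene was low in Test1 alone. For XPNPEP3 and DNAH9 the mean in CON lay between those in Test1 and Test2. Of the 12 fits that each left out 1 array, IGFLR1 passed in all, XPNPEP3 in 4, DNAH9 in 8 and FBXL16 in 9. A_73_100847 rose by 1.96 ± 0.23 (adjusted p = 0.0281, 0.115 with the block) and A_73_P081658 fell by 2.30 ± 0.23 (adjusted p = 0.0123). ULBP3 stood at -2.98 ± 0.41, ZPR1 at -0.82 ± 0.12 and FSTL1 at -1.17 ± 0.19 (adjusted p = 0.0871, 0.139 and 0.181). Of the probes, 6 passed (5 higher, 1 lower) and 2012 had an unadjusted p under 0.05. T cell genes changed by -0.29 (adjusted p = 9.15e-06) and phagosome genes rose by 0.20 (adjusted p = 0.000111), each with an adjusted p = 0.324 with an estimated correlation, beside erythroid genes at 0.66 (adjusted p = 0.000661, adjusted p = 0.387 with an estimated correlation). The phagosome and erythroid lists moved this way on 2 of 3 slides. In all 13 lists rose and 5 fell, none of them with an estimated correlation (lowest adjusted p = 0.324) or with fry (2 with fry and the slide block). Apoptosis genes (0.11) did not pass with the slide block (adjusted p = 0.0311, 0.0643 with the block, adjusted p = 0.324 with an estimated correlation). The count of 6 became 65 without Test1 replicate 2 (9 higher, 56 lower) and 1 without Test2 replicate 1 or 2.

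Whether the PCR difference depended on ELISA status was tested as an interaction over all 12 animals. No probe passed in limma, with or without the slide block, and 625 had an unadjusted p under 0.05. In the deposited matrix 5 passed (0 with the slide block), and 1 passed without CON replicate 2 (0 with the slide block). RNF141 and BOLA-DYB stood at 1.33 ± 0.23 and 1.41 ± 0.27, and SPDEF, B3GNT3 and ZPR1 at -1.38 ± 0.33, -0.99 ± 0.26 and -0.65 ± 0.17 (SE, adjusted p = 1 for each). Ribosomal protein genes had a difference of -0.23 (72 of 72 below 0, adjusted p = 2.75e-10, adjusted p = 0.693 with an estimated correlation), which was -0.38 without Test2 replicate 1, -0.15 without CON replicate 1, -0.13 without Test1 replicate 3, and -0.14 without Test2 replicate 3 or Test3 replicate 1. MHC class II genes had one of 0.56 (9 of 14 above 0, adjusted p = 0.000422, adjusted p = 0.548 with an estimated correlation), with a median of 0.21 and 1 member higher adjusted over the list alone. Their lower mean in Test1 against CON came largely from BOLA-DQA5, which was high in CON replicates 1 and 3 only. In all 8 lists were higher and 4 lower, none of them with an estimated correlation (lowest adjusted p = 0.548) or with fry (lowest adjusted p = 0.882). Monocyte genes (-0.31) and immediate early genes (0.15) did not pass with the slide block (adjusted p = 0.0927 for both, against 0.021 and 0.035 without; with an estimated correlation, adjusted p = 0.693 and 0.608).

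The 3 comparisons against CON shared their control animals. Across probes, the log2 fold changes of Test2 and Test3 correlated at 0.857, against 0.499 in 20 simulations of unchanged groups with shared controls. Those of Test1 correlated at 0.526 with Test2 (simulated 0.501) and at 0.491 with Test3 (simulated 0.499). The covariance was 0.162 for Test2 and Test3, 0.0704 for Test1 and Test2 and 0.073 for Test1 and Test3, against 0.0581, 0.0583 and 0.0581 in the simulations. With the slide block, all 3 probes higher in Test2 were among the 257 higher in Test3 (0.0234 for independent lists), and both lower ones were among the 160 lower in Test3 (0.00973 for independent lists). The 3 controls were too few to be divided between the comparisons, so part of the excess of these overlaps over independent lists may come from the shared controls.

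**Figure D3:**
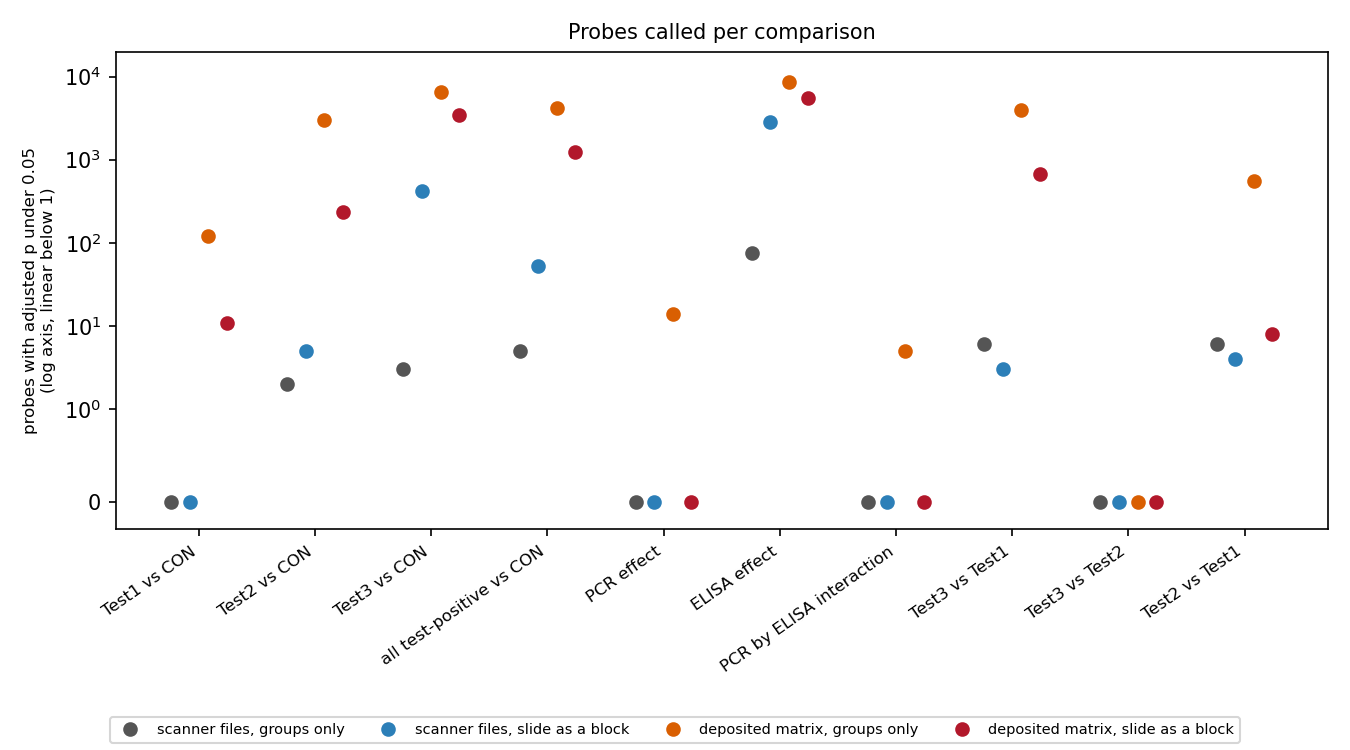
Number of probes with an adjusted p under 0.05 (y axis, log scale, linear below 1) for each of the 10 comparisons (x axis), from the scanner files and from the deposited matrix, each fitted with groups only and with the slide as a block. For ELISA status the 4 counts were 75, 2873, 8685 and 5463.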

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

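The tests of lymphocyte and monocyte shares, of a slide or array fault and a sequence difference at IGFLR1, and of slide means and quantile normalization in the deposited matrix were chosen after the results were seen. The following 12 gene lists drew attention because the PCR difference was not the same in ELISA-positive and ELISA-negative cattle by an interaction test. Each value is the mean log2 difference between the 2 PCR effects, with the camera adjusted p. They were ribosomal proteins (-0.232, 2.75e-10), interferon-gamma response (0.222, 0.000219), T cell (-0.246, 0.000422), MHC class II (0.556, 0.000422), cell cycle (0.169, 0.00163), sterol (-0.215, 0.00221), monocyte (-0.313, 0.021), neutrophil (0.228, 0.0313), apoptosis (0.0954, 0.0313), B cell (0.135, 0.035) and immediate early genes (0.147, 0.035). The type I interferon list had a mean of 0.00702, a median of 0.165 and an adjusted p of 0.00144. With an estimated correlation none of the 12 passed (adjusted p from 0.548 to 0.693).

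Many of these 12 calls depended on single animals. Of the 12 fits that each left out 1 array, the call held in 12 for ribosomal, interferon-gamma and MHC class II genes, 11 for type I interferon, 9 for T cell, 8 for cell cycle, sterol and monocyte, 5 for neutrophil, B cell and immediate early and 4 for apoptosis genes. The mean ranged from -0.380 without Test2 replicate 1 to -0.134 without Test1 replicate 3 for ribosomal genes, and from 0.106 without Test1 replicate 1 to 0.343 without Test3 replicate 1 for interferon-gamma genes. It ranged from -0.378 without CON replicate 1 to -0.125 without CON replicate 2 for T cell genes, and from 0.433 without Test3 replicate 2 to 0.768 without Test3 replicate 1 for MHC class II genes. For type I interferon genes it ranged from -0.128 without Test2 replicate 1 to 0.205 without Test2 replicate 3, and for cell cycle genes from 0.00477 without Test3 replicate 1 to 0.299 without Test3 replicate 3. Sterol genes ranged from -0.307 without Test2 replicate 1 to -0.126 without Test3 replicate 1, and neutrophil genes from 0.0842 without Test1 replicate 1 to 0.357 without Test1 replicate 2. Apoptosis genes ranged from 0.0546 without Test1 replicate 1 to 0.148 without Test1 replicate 2, and immediate early genes from 0.0765 without CON replicate 2 to 0.249 without CON replicate 1. Single values far from the others were not tested for here.

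Splits of the animals were compared with the real groups. For ELISA status 2 of 100 splits, the real one included, gave at least the 75 probes of the real groups. The other one gave 763 and put all arrays of slide 2 with Test2 and Test3 replicate 1 against all arrays of slide 3 with CON and Test1 replicate 1, so it followed slides and points to a structure of the samples; the count with the slide as a block was 2873. Within slides, 2 of 100 splits gave at least 2873, and the other one, which exchanged Test1 replicate 2 and Test2 replicate 2, gave 4211. For all test-positive animals against CON 2 of 100 splits gave at least 5 (highest other 7), and with the slide block 1 of 64 gave at least 53 (highest other 9). Few splits thus reached these 4 counts, which makes a random grouping less likely but does not exclude it. The splits for the counts of 75 and 5 ignored the slides, over which the real groups were balanced. PCR status and the interaction had 0 probes, so that 100 of 100 splits gave at least as many whatever the groups, and the splits tested nothing there. Their highest other counts were 3 and 244, the second in the same slide-following split.

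For the comparisons of 3 animals with 3, the 10 splits are too few for a share under 0.05. The splits with at least the real count, the real count and the highest other were 10, 0 and 1 for Test1 against CON, 1, 2 and 0 for Test2 against CON, 1, 3 and 1 for Test3 against CON, 1, 6 and 1 for Test3 against Test1, 10, 0 and 23 for Test3 against Test2, and 1, 6 and 1 for Test2 against Test1.

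In ELISA-positive cattle myeloid lists were higher and lymphocyte lists lower. Array brightness as the cause was argued against by its like means in ELISA-positive and ELISA-negative arrays (10.88 ± 0.31 and 10.88 ± 0.20 on the log2 scale, SD). With brightness as a covariate 100% (100.4) of the difference between monocyte and T cell scores was kept (1.13, 95% CI 0.533 to 1.73). A covariate alike in both groups could not have removed it, so this adds no support. A lower share of lymphocytes alone stays open: the monocyte list rose by 0.431 more than the neutrophil list, with an exact permutation p of 0.0741. A higher share of monocytes stays open as well: 100% of 22 monocyte markers lay above 0, but this restates the pattern and gives it no support. Cell counts were not used here, so cell shares and expression within cells cannot be told apart.

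IGFLR1 was far lower in ELISA-negative than in ELISA-positive cattle, and well above background in all 12 animals. A change of the whole region was argued against by 7 measured of 10 neighbouring genes, with a median of 0.122 (-0.665 to 0.597). The smallest gap between ELISA groups within a slide was 3.14 on the log2 scale, so the difference was seen on each of the 3 slides. The rule for named genes asked for groups without overlap, so a gap above 0 was fixed in advance. It is therefore no test of a fault of 1 slide or array. A sequence difference under the probe stays open, because the array had 0 further probes for the gene.

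The deposited matrix gave 8685 probes for ELISA status against 75. Removal of slide means before deposit was in keeping with a mean correlation of -0.283 between deviations of same-slide arrays. Quantile normalization alone was argued against, since it gave 2% (2.00) as many calls (174 probes). More than slide means may have been removed, as the residual SD after group and slide was 0.848 times that of quantile-normalized values. No biological explanation was tested for this pattern.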

How the results depend on the processing

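The fits of counts with the slide block under other normalizations, in the deposited matrix and without single arrays were chosen after seeing the data. Across alternatives, 149 counts stayed within 1.5 times and 139 did not. For lists 2869 values kept direction and side of the threshold, 124 came to pass and 219 no longer passed (61 of them with an estimated correlation and 46 with fry). Another 173 list values changed direction without passing in either fit, and 3 changed direction where 1 of the fits had passed. For named genes 11070 values kept both, 644 came to pass, 157 no longer passed and 41 changed direction without passing in either fit. The cause was not tested for any of the following. Counts are in the order Test1, Test2, Test3 and all test-positive against CON, then as named. The deposited matrix gave 122, 2994, 6567 and 4145, with 14 for PCR, 8685 for ELISA, 5 for the interaction, 3941 for Test3 against Test1 and 558 for Test2 against Test1. With the slide block the matrix gave 11, 237, 3414 and 1251, with 5463 for ELISA. It then gave 0 for PCR and 0 for the interaction, 670 for Test3 against Test1 and 8 for Test2 against Test1. Normexp on the median signal, then quantile, gave 4, 4, 5 and 10, with 118 for ELISA and 16 for Test3 against Test1. Of these 118 probes, 53 were among the 75 reported for ELISA status, and 4 of the 16 were among the 6 reported for Test3 against Test1. Array weights gave 20, 15, 1183 and 498, with 2039 for ELISA, 53 for Test3 against Test1 and 12 for Test2 against Test1. The arrays of the compared groups alone gave 2 for Test1, 61 for Test2, 0 for Test3 against Test1 and 1 for Test2 against Test1. An unadjusted p under 0.05 with a 2-fold change gave 303, 651, 924 and 487, with 65 for PCR, 541 for ELISA, 256 for the interaction, 558 for Test3 against Test1, 56 for Test3 against Test2 and 406 for Test2 against Test1. An adjusted p under 0.10 gave 5, 4, 69 and 38, with 1250 for ELISA and 15 for Test3 against Test1. The replicate block (slide as a block) gave 5 for Test2, 417 for Test3, 53 for all test-positive, 2873 for ELISA and 3 for Test3 against Test1. Trend and robust eBayes gave 19 for Test3, 8 for all test-positive, 297 for ELISA and 14 for Test3 against Test1. Quantile normalization gave 3 for all test-positive and, with the slide block, 849 for Test3. Probes well above background on all 12 arrays gave 3 for all test-positive and 137 for ELISA, the mean of the probes of a gene 10 for all test-positive, and no filter on dim probes 25 for ELISA. Of the 75 probes reported for ELISA status, 65 were among the 137 and 22 among the 25. The share of higher probes for ELISA was 52% (39 of 75). It was 44% in the matrix and 49.1% to 53.4% under the other normalizations, 64% with no filter, 59.6% with the mean of the probes of a gene, 58.3% with array weights, 57.2% with trend and robust, and 48% to 77.8% without 1 array. Leaving out 1 array gave 0 to 3 for Test1, 1 to 14 for Test2, 1 to 296 for Test3, 0 to 140 for all test-positive, 6 to 1221 for ELISA, 0 to 1 for the interaction, 1 to 194 for Test3 against Test1 and 1 to 65 for Test2 against Test1. With the slide block it gave 0 to 2144 for Test3, 0 to 1206 for all test-positive and 1 to 4972 for ELISA. In the interaction, 3 lists reversed the direction of their test, while their mean values ranged as follows: monocyte genes (-0.562 without Test1 replicate 1 to -0.0435 without Test1 replicate 2), B cell genes (0.350 without Test1 replicate 1 to -0.121 without Test1 replicate 2) and NK genes (0.0665 without Test3 replicate 2 to -0.330 without Test3 replicate 1). IGFLR1 passed for ELISA status, Test2 and Test3 in each of the 12 fits without 1 array, with ELISA values from 4.02 to 4.34. Between 68.5% and 74.6% of the spots per array were well above background, and probes well above background on fewer than 3 of the 12 arrays were tested only in the fit with no filter.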

Other observations

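The exact permutation of ELISA labels within slides was chosen after the results were seen. JSP.1, an MHC class I gene, stood at -1.18 in CON replicate 1 and -3.61 in Test1 replicate 2, and between 7.49 and 8.14 in the other 10 cattle (log2 signal relative to the array). BOLA-DQA5, an MHC class II gene, stood at 3.65 and 2.48 in CON replicates 1 and 3 and between -5.36 and -1.12 in the other 10. WC1.3 and CD163L1, genes of gamma-delta T cells, had their lowest values in Test1 replicate 2 (-1.89 and 0.721) and their highest in Test1 replicate 1 (2.31 and 4.98).

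The monocyte score of Test1 replicate 2, the array with the lowest share of spots well above background (68.5%), was 0.392, against -0.644 and -0.187 in Test1 replicates 1 and 3. The erythroid score of Test3 replicate 1 was -0.663, against 1.19 and 0.439 in Test3 replicates 2 and 3, and that of Test2 replicate 1 was -0.509, against 0.657 and 1.01 in Test2 replicates 2 and 3.

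In the exact permutation over the 216 assignments of ELISA labels within slides (smallest possible p 0.00926), 13 of 28 lists passed after adjustment. The monocyte list had an adjusted p of 0.0399, the granule list 0.0556, the erythroid list 0.0915 and the gamma-delta list 0.101. Apoptosis and immediate early genes, which did not pass with camera, had an adjusted p of 0.0399.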
